A study of Mus musculus with 6 samples.

How the data were processed

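Total RNA of cultured fetal mouse ovaries was sequenced, with 3 libraries of ovaries cultured with 15 µM NAPQI and 3 of ovaries cultured with ethyl acetate. Samples were grouped by their titles. The authors deposited a table of read counts per gene, whole numbers with no normalization per the file headers and the values. The same deposited table holds FPKM values, which were checked to be the count per kilobase of the length given there and per 1e+06 counted reads, and which were not used for tests. The submitters named FastQC 0.11.8, HISAT2 2.0.5 and HTSeq 0.9.1 and the genome build GRCm39, and settings and strandedness were not given in the sources used here. A second deposited table holds the authors' comparison of NAPQI with control. Its signal columns are, per the file headers, the authors' mean normalised counts over all libraries or per group. Its fold change column is the authors' ratio of these means, and its log2 column is the binary logarithm of that ratio, as deposited. Its p-value columns hold the authors' unadjusted and adjusted p; the column and file names point to DESeq, with no version in the sources used here. Each table had 1 empty line, which was not analysed here.

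Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and groups were compared by the two-sided quasi-likelihood F-test with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values in the text use the TMM-scaled library sizes. Errors of log2 fold changes are standard errors of the fit, and errors of CPM are SD over 3 libraries. In a rank test 3 libraries against 3 cannot give a two-sided p under 0.1, so the model fitted across all genes was used.

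The 33 gene lists, the tests and the rule for named genes were set before the data were examined. The lists were tested by camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with an estimated correlation and with fry beside it, each adjusted over the lists. Of 760 list genes, 5 were not in the table. The glycolysis list has 31 tested identifiers for 30 symbols, since Aldoa has more than 1. The named genes were Sirt7; of the genes with an adjusted p under 0.05, a mean of at least 1 CPM and no overlap between groups, the 6 with the largest and the 6 with the smallest log2 fold change; and the 2 members with the smallest p of each of the 8 lists with the smallest camera p and of each of the meiotic lists. The smallest changes are those that fell, and 1 gene did. The values of 1 gene that the rule names are not reported here.

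The alternatives were other scalings (DESeq2 size factors, upper quartile, library size alone), no low-count filter, a filter of 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, the exact test of edgeR, the replicate number as a block, other thresholds, camera on ranks, and each library left out in turn. Removal of each library's trend on transcript length or GC content (lowess, span 0.3) was added after the data were seen. Transcript length here means the length given per gene with the deposited counts, which need not be that of a single transcript. The share of a list's median that was kept was given with the bounds of a bootstrap over the members. GC content was taken from the longest transcript of each gene in an older annotation matched by gene identifier, which gave a value for 99.89% of tested genes; coordinates are those of the deposited table. The replicate numbers gave no sign of pairing: 0 of the 3 same-numbered pairs had a correlation of deviations from the group means over 0.1. Control replicate 2 with NAPQI replicate 3 was at 0.212 and control replicate 1 with NAPQI replicate 2 at 0.133. A pairing under other numbers is therefore not excluded. The gene test, the list test and the length correction were also tested on simulated data, in which known changes were added to counts. The gene test recovered 49.3% of 67 genes changed 1.5-fold, 76.1% of 67 changed 2-fold and 95.5% of 66 changed 4-fold. There were 12 false calls among 159. The real comparison made only 12 calls in all, and with fewer calls the adjustment asks for a smaller p. These recovered shares therefore do not carry over to it. A list shifted by 0.3 on the log2 scale was called (camera adjusted p = 1.11e-06), and so was 1 other list. Genes were drawn independently, so this could not check the list test under correlation between genes. The Spearman correlation of an added length trend went from 0.434 to 0.001.

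Depth was 13879347 to 17258609 counts per library. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.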

Results

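Gene expression was measured by RNA sequencing in cultured fetal mouse ovaries. Ovaries were taken at 14.5 days post coitum, an age at which female germ cells enter meiosis, and were kept for 3 days in serum-free medium. The medium contained 15 µM N-acetyl-p-benzoquinone imine (NAPQI), the oxidising and protein-binding metabolite of acetaminophen, or the same volume of ethyl acetate, the solvent, as the control. Each group had 3 libraries of total RNA from wild-type ovaries. Whether the 3 came from separate litters or cultures was not given in the sources used here, so the p-values measure the spread between these libraries, which may be technical. Summed counts per library were 17127736, 17258609 and 13879347 for control replicates 1, 2 and 3, and 16050342, 15652213 and 14288452 for NAPQI replicates 1, 2 and 3. Of 21898 genes in the count table, 14736 had enough counts to be tested. Control replicate 3 stood farthest from the other libraries on the first principal component, which held 33.47% of the variance, at -35.68 against -14.93 to 26.35 for the rest. The groups also lay apart on this component, with controls at -35.68 to 3.89 and NAPQI libraries at 8.8 to 26.35. Control replicate 3 also had the lowest depth and the highest share of globin counts, 0.0197% against 0.0022% to 0.0069%.

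The main question was which transcripts differ between ovaries cultured with NAPQI and ovaries cultured with the solvent. With NAPQI, 11 genes rose and 1 fell. The largest rise was that of Wif1, a secreted inhibitor of Wnt signalling, which went from 0.816 ± 0.118 to 3.87 ± 0.396 counts per 1e+06 counted reads (CPM; mean ± SD, n = 3). The most certain rise was that of Stc2, which encodes the secreted glycoprotein stanniocalcin 2 and is a target of the integrated stress response, from 34.5 ± 2.24 to 78.4 ± 10.2 CPM. Ccn1, which encodes a secreted protein of the extracellular matrix, fell from 277 ± 119 to 87.9 ± 18.7 CPM. For each of these 12 genes all 3 NAPQI libraries lay on the same side of all 3 controls.

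Stc2 had a log2 fold change of 1.18 ± 0.11 (SE) and an edgeR adjusted p of 0.0021. Among the genes named by the rule fixed beforehand, Wif1 rose by 2.24 ± 0.35 on the log2 scale with an edgeR adjusted p of 0.0394. Genes of ion channels were next. Asic4, a member of the acid-sensing ion channel family, rose by 2.05 ± 0.31, and Trpc4, a cation channel subunit, by 1.67 ± 0.25. Rai2, a retinoic acid-induced gene, rose by 1.30 ± 0.20. Each of these 3 had an edgeR adjusted p of 0.0394. Ptprb, the receptor tyrosine phosphatase of vascular endothelium, rose by 1.04 ± 0.17 with an edgeR adjusted p of 0.0489. Ccn1 fell by 1.66 ± 0.27 with an edgeR adjusted p of 0.048.

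The other 5 genes that rose lay below a doubling and outside the rule, and were named after their values were seen. Hunk, which encodes a protein kinase, rose by 0.91 ± 0.14 on the log2 scale. Dpp6, an auxiliary subunit of potassium channels, also rose by 0.91 ± 0.14. Angpt2, a ligand of the endothelial receptor TIE2, rose by 0.90 ± 0.13. Ccnjl, a cyclin-like gene, rose by 0.77 ± 0.12 and Slc35f1, a solute carrier gene, by 0.68 ± 0.11. Their edgeR adjusted p was 0.0394, except for Slc35f1 at 0.0489. Ptprb and Angpt2 act in vessels. The 16 endothelial marker genes had a median log2 fold change of 0.02 as a group and were not called (camera adjusted p = 0.553). Without control replicate 3 they were called higher at the preset correlation (camera adjusted p = 0.00283). With all libraries and an estimated correlation the camera adjusted p was 0.993.

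**Figure D1:**
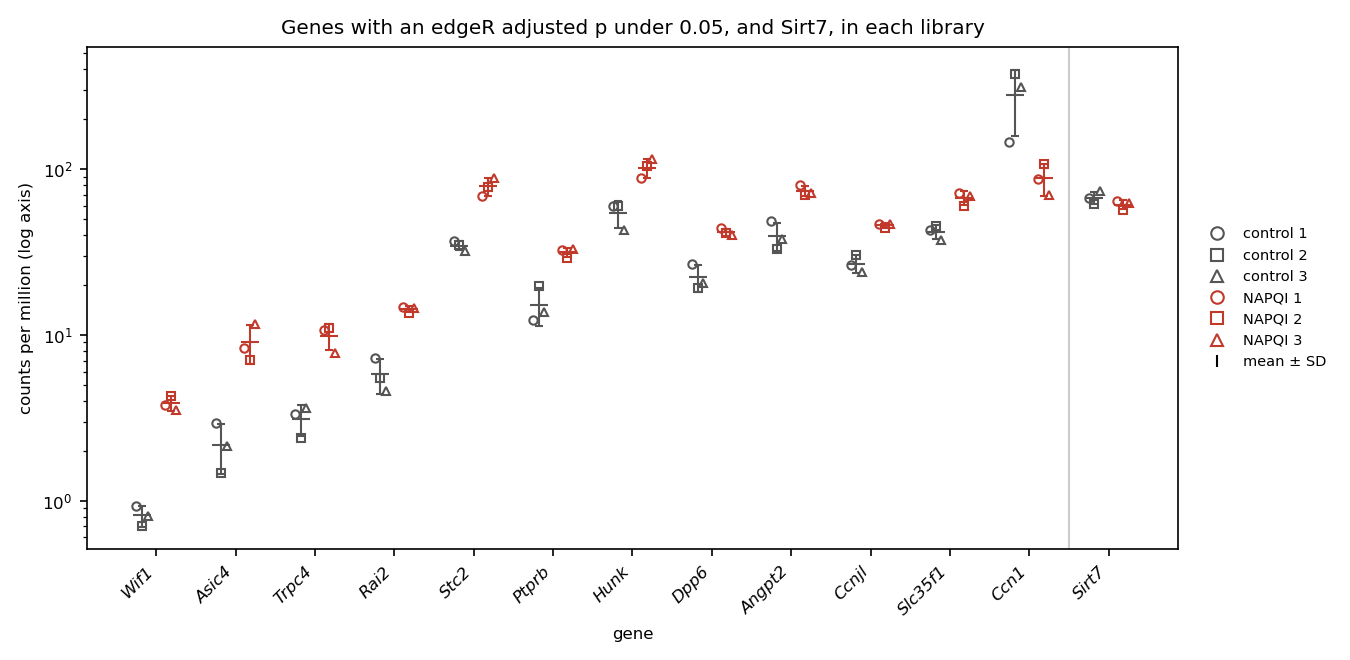
CPM (log axis) of the 12 genes with an edgeR adjusted p under 0.05, ordered by fold change, and of Sirt7 at the right, for the 3 control libraries (grey) and the 3 NAPQI libraries (red). Each symbol is a library and the horizontal tick with whiskers is the mean ± SD of a group; the groups do not overlap for the 12 genes and overlap for Sirt7.

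In GRCm39 coordinates as given in the deposited table, Stc2 (ENSMUSG00000020303) lies on chromosome 11 from 31307307 to 31320074 on the minus strand. Ccn1 (ENSMUSG00000028195) lies on chromosome 3 from 145352731 to 145355736 on the minus strand. The genes Wif1 (ENSMUSG00000020218, chromosome 10, 120869865 to 120936555), Asic4 (ENSMUSG00000033007, chromosome 1, 75427080 to 75450987), Trpc4 (ENSMUSG00000027748, chromosome 3, 54063456 to 54225892), Rai2 (ENSMUSG00000043518, chromosome X, 160500065 to 160562492) and Ptprb (ENSMUSG00000020154, chromosome 10, 116111428 to 116225440) lie on the plus strand. Angpt2 lies within the span of Mcph1 and Dpp6 overlaps Speer4b, and whether counting used the strand was not given in the sources used here, so the counts of both may include reads of the other gene. Mcph1 moved the same way as Angpt2. Its log2 fold change was 0.63 by DESeq2 (adjusted p = 0.000656) and 0.62 by the exact test of edgeR (adjusted p = 0.000567). The quasi-likelihood test did not call it (edgeR adjusted p = 0.0875). Whether shared reads link the genes was not tested.

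Most transcripts differed little between the groups. Of the tested genes, 92.16% had an absolute log2 fold change under 0.5, and 7 of the 12 genes that passed had one of 1 or more. An unadjusted p under 0.05 was seen for 1362 genes, 621 higher and 741 lower. The libraries of the groups did not overlap for 2121 genes, 14.39% of those tested, where chance gives 10%. The count of 12 rested on single libraries: it was 1 without control replicate 3, NAPQI replicate 1 or NAPQI replicate 3, 58 without control replicate 2, 25 without NAPQI replicate 2 and 18 without control replicate 1. It also differed between tests, with 80 genes by DESeq2, 115 by the exact test of edgeR, 48 without a low-count filter and 1 by limma-voom, and Stc2 was called in 19 of 19 settings.

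The next question was whether groups of functionally related genes moved together. Of 33 lists fixed before the data were examined, 5 were called lower and 2 higher with NAPQI by camera with a preset correlation between genes of 0.01. The list of immediate early genes, which are induced within minutes of a stimulus, had the lowest median, 0.315 of the control level. The lists of inflammatory genes and NF-kB targets, macrophage markers, cytosolic ribosomal proteins and nuclear-encoded subunits of the respiratory chain were also called lower. The lists of cholesterol synthesis and of DNA double-strand break repair were called higher, with small medians. No member of the 7 lists passed over all genes by the quasi-likelihood test of edgeR in the main fit. None of the 7 held with a correlation estimated from the data. There the camera adjusted p was 0.993 for every list, and 0 lists had an unadjusted p under 0.05. That correlation was estimated from only 6 libraries, so the loss does not decide whether a list moved. By library, the mean log2 CPM of the members overlapped between the groups for each of the 7 except the immediate early list.

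All 16 tested immediate early genes had a negative log2 fold change, with a median of -1.67 (camera adjusted p = 1.32e-11, and adjusted p = 0.993 with an estimated correlation). For 12 of them all 3 NAPQI libraries lay below all 3 controls. Adjusted over the list alone, 14 were lower. Over all genes, 0 were called by the quasi-likelihood test of edgeR, 14 had an unadjusted p under 0.05, and DESeq2 called 2 and the exact test of edgeR 7. The quasi-likelihood test with no low-count filter called 5, Dusp1, Zfp36, Nr4a1, Jun and Egr3. Dusp1, a phosphatase of MAP kinases, had a log2 fold change of -1.63 ± 0.35 (edgeR adjusted p = 0.181), and Dusp6, a phosphatase of ERK, one of -0.85 ± 0.20 (edgeR adjusted p = 0.262). The span of Dusp1 overlaps Ergic1. The NAPQI libraries differed from each other on this list. Fos, a subunit of the transcription factor AP-1, stood at 274, 284 and 411 CPM in the controls, at 9.25 and 11.3 CPM in NAPQI replicates 1 and 3, and at 199 CPM in NAPQI replicate 2. Fosb stood at 4.16 and 3.11 CPM in NAPQI replicates 1 and 3 and at 232 CPM in NAPQI replicate 2, within the control range of 194 to 429 CPM. Without NAPQI replicate 2, 11 immediate early genes were called lower and the median was -2.61, and Dusp1 passed with an edgeR adjusted p of 3.33e-05 (up to 0.759 over the alternatives). Dusp6 passed without control replicate 1, at 0.0244 (0.0162 to 0.979 over the alternatives).

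**Figure D2:**
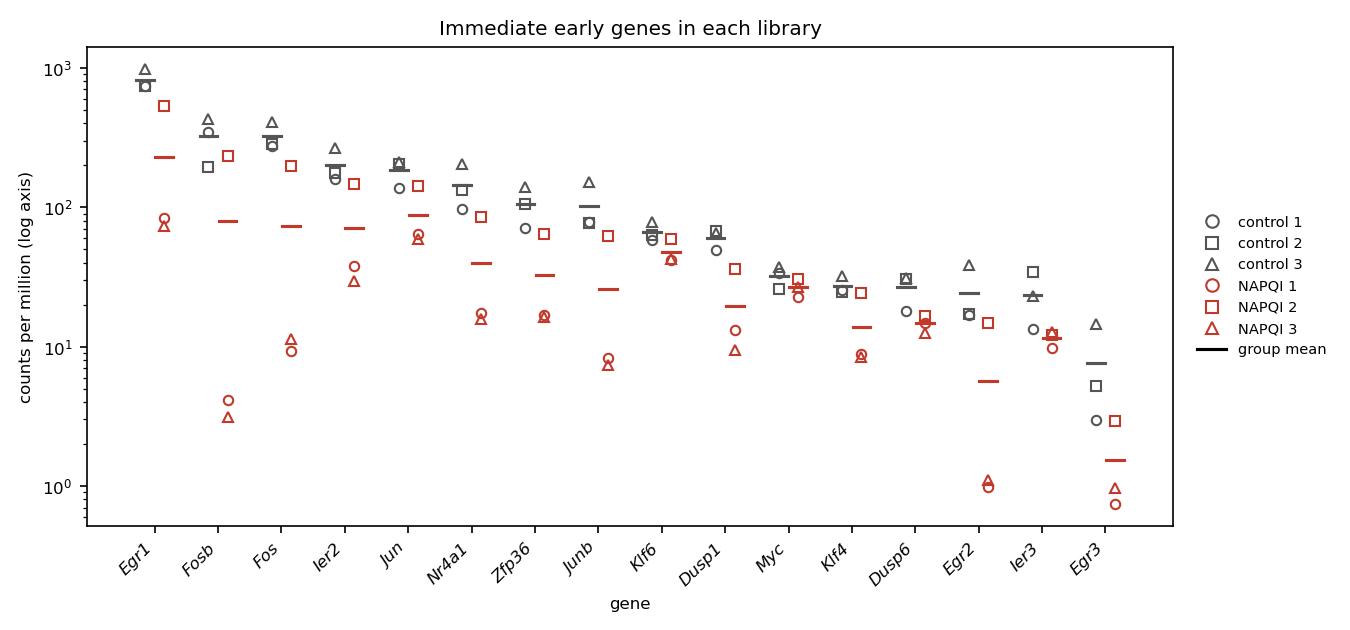
CPM (log axis) of the 16 tested immediate early genes in the 3 control libraries (grey) and the 3 NAPQI libraries (red); each symbol is a library and each horizontal line the mean of a group. NAPQI replicate 2 (red squares) lies near the controls, for example 199 for Fos, while NAPQI replicates 1 and 3 lie far below for most of these genes.

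Of 23 listed inflammatory genes and NF-kB targets, 14 had enough counts to be tested. Of these 14, 13 had a negative log2 fold change, with a median of -0.71 (camera adjusted p = 0.000291, and adjusted p = 0.993 with an estimated correlation). None passed over all genes by the quasi-likelihood test of edgeR or by DESeq2, and 0 passed adjusted over the list alone; 6 had an unadjusted p under 0.05, all lower. The NF-kB target Tnfaip3 had a log2 fold change of -0.99 ± 0.32 (edgeR adjusted p = 0.389) and Nfkbia, the inhibitor of NF-kB, one of -0.40 ± 0.13 (edgeR adjusted p = 0.393). Ccl2, Cxcl5, Cxcl10, Ptgs2 and Saa3, at -0.71 to -1.58, had control means of only 1.77 to 3.28 CPM. Nfkb1, Nfkb2 and Relb, with Nfkbia the most abundant members, were at -0.11, -0.16 and -0.46. The median of the list was -0.40 without control replicate 3 and -0.45 without NAPQI replicate 3. The list was called with each library left out in turn at the preset correlation, but its library means overlapped between the groups. Control replicate 1 was at 2.266 log2 CPM, below NAPQI replicates 1 and 2 at 2.297 and 2.377. Control replicate 3 was highest, at 3.257, and NAPQI replicate 3 lowest, at 1.939.

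The macrophage and leukocyte markers had a median log2 fold change of -0.32, with 14 of 16 negative (camera adjusted p = 0.00672, and adjusted p = 0.993 with an estimated correlation). Over all genes and adjusted over the list alone, 0 passed, and 4 had an unadjusted p under 0.05. C1qc, a complement component made by macrophages, stood at 19.7 ± 4.56 CPM in controls and 13.3 ± 1.63 CPM with NAPQI (edgeR adjusted p = 0.406). Cd68, a lysosomal protein of macrophages, stood at 18.7 ± 4.42 and 13.1 ± 1.30 CPM (edgeR adjusted p = 0.429). The list was not called without control replicate 1 (camera adjusted p = 0.104) or without NAPQI replicate 3 (camera adjusted p = 0.0689, with a median of -0.16).

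Among cytosolic ribosomal proteins, 48 of 52 had a negative log2 fold change, with a median of -0.11 (camera adjusted p = 0.0111, and adjusted p = 0.993 with an estimated correlation). Among nuclear-encoded respiratory chain subunits it was 34 of 42, with a median of -0.13 (camera adjusted p = 0.0128, and adjusted p = 0.993 with an estimated correlation). Both had 0 genes called over all genes or adjusted over the list alone, and 1 with an unadjusted p under 0.05. Rpl26 had a log2 fold change of -0.62 ± 0.25, Rps15 of -0.30 ± 0.15, Cyc1 of -0.26 ± 0.10 and Ndufs3 of -0.16 ± 0.09, with edgeR adjusted p of 0.476, 0.549, 0.49 and 0.589. Ndufs3 shares its span with Kbtbd4, and Rpl26 and Rps15 may share reads with processed pseudogenes. The lengths given for the genes of both lists are short, and over all tested genes the log2 fold change went with this length (Spearman correlation across genes 0.216; genes are not independent replicates). The median went from -0.106 in the tenth with the shortest transcripts to 0.060 in the tenth with the longest. Control replicate 3 stood apart on length, with a Spearman correlation of -0.3 across genes between transcript length and its deviation from the mean log2 CPM of all libraries, against -0.099 to 0.167 in the other libraries. Without control replicate 3, the median was -0.013 for the ribosomal and -0.024 for the respiratory list, with a camera adjusted p of 0.881 and 0.764. With the length trend removed the medians were -0.023 and -0.035 and the camera adjusted p 0.385 and 0.521. The ribosomal call also ended without control replicate 2 (0.122), NAPQI replicate 1 (0.195) or NAPQI replicate 2 (0.124), and the respiratory call without NAPQI replicate 1 (0.293) or NAPQI replicate 2 (0.124). Other libraries left out moved the lists the other way: without control replicate 1 the ribosomal median was -0.23, with 52 of 52 negative (1.48e-10), and without NAPQI replicate 3 it was -0.20, also with 52 of 52 (9.78e-07). The respiratory list was at 0.000334 and 4.89e-06 in these fits.

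Of the 23 genes of cholesterol synthesis, 19 had a positive log2 fold change, with a median of 0.15 (camera adjusted p = 0.0144, and adjusted p = 0.993 with an estimated correlation). Hsd17b7 had a log2 fold change of 0.32 ± 0.11 (edgeR adjusted p = 0.416). None passed over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. The call ended without control replicate 1 (0.688, with a median of 0.08), NAPQI replicate 1 (0.145) or NAPQI replicate 3 (0.138). The median rose to 0.25 without control replicate 2 (3e-04) and to 0.23 without NAPQI replicate 2 (0.00025).

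The series concerns meiosis, and the meiotic lists moved little. The 44 genes of DNA double-strand break repair and checkpoint had a median log2 fold change of 0.09, with 32 positive (camera adjusted p = 0.0199, and adjusted p = 0.993 with an estimated correlation). The checkpoint kinases Atm and Atr had log2 fold changes of 0.39 ± 0.15 and 0.27 ± 0.12 (edgeR adjusted p = 0.447 and 0.512). None of the 44 passed over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05. The lengths given for the genes on this list are long, with a median of 5763 nucleotides against 4436 for all tested genes. With the length trend removed the list stayed called at the preset correlation (camera adjusted p = 0.0462, with a median of 0.07). The call ended without control replicate 1 (0.179), control replicate 3 (0.199, with a median of 0.04) or NAPQI replicate 3 (0.34, with a median of 0.04). The median was 0.18 without control replicate 2 (0.0011) and 0.11 without NAPQI replicate 1 (0.00341). The call also ended with the GC trend removed (0.092, with a median of 0.06) and with the length and GC trends removed (0.131). The 30 genes of meiotic break formation and recombination had a median of 0.05 (camera adjusted p = 0.0924), the 13 of meiotic entry and cohesin also 0.05 (0.496), and the 14 of the synaptonemal complex and axis -0.013 (0.981). In these 3 lists 0 genes passed over all genes by the quasi-likelihood test of edgeR, by DESeq2 or adjusted over the list alone, and 3 had an unadjusted p under 0.05. The recombination list was called higher at the preset correlation without control replicate 2 (0.0166) or NAPQI replicate 1 (0.0115) and with the length trend removed (0.0462). With all libraries and an estimated correlation its camera adjusted p was 0.993. The median of the meiotic entry list was 0.16 without control replicate 2, with 12 of 13 positive (0.094), 0.13 without NAPQI replicate 1 and 0.007 without control replicate 3. The median of the synaptonemal list changed sign with the library left out, from -0.11 without control replicate 1 to 0.10 without NAPQI replicate 1.

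None of the single meiotic genes named by the rule passed over all genes by the quasi-likelihood test of edgeR. Rec8, the meiosis-specific cohesin subunit, stood at 23.4 ± 4.04 CPM in controls and 16.4 ± 1.46 CPM with NAPQI, with all 3 NAPQI libraries below all controls (log2 fold change -0.51 ± 0.16, edgeR adjusted p = 0.364). Ythdc2, an RNA helicase needed for the switch to meiosis, had a log2 fold change of 0.31 ± 0.10, with all 3 NAPQI libraries above all controls (edgeR adjusted p = 0.402). Spo11, which makes the meiotic breaks, had one of 0.26 ± 0.13 (edgeR adjusted p = 0.549), and Mlh3, which marks crossovers, one of 0.25 ± 0.10 (edgeR adjusted p = 0.447), both also without overlap between the groups. Of the synaptonemal complex genes, Sycp3 had a log2 fold change of 0.21 ± 0.14 and Tex12 of -0.20 ± 0.14 (edgeR adjusted p = 0.649 and 0.654). Sycp3 overlaps Chpt1 and Tex12 overlaps Il18 in the table.

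Lists of the germ line and of the other cells of the ovary were not called. Median log2 fold changes were 0.10 for germ cell identity and the piRNA pathway (camera adjusted p = 0.0792), 0.02 for primordial germ cells and pluripotency (0.838), -0.12 for oocyte growth (0.266), -0.03 for pregranulosa cells (0.838), -0.05 for the surface epithelium (0.838) and 0.02 for endothelium (0.553). For stroma and mesenchyme the median was -0.17 (0.0544), with Col3a1 at -0.37 ± 0.12 and Mgp at -0.56 ± 0.18 (edgeR adjusted p = 0.403 and 0.401). Markers of cells that the dissected tissue could also hold had medians of -0.26 for the mesonephros (0.496), -0.22 for fetal testis and steroidogenic cells (0.0924) and -0.62 for erythroid cells (0.187). Adjusted over the list alone, 1 pregranulosa gene, Aard, was lower, at -0.59 ± 0.13, and 0 were called over all genes by the quasi-likelihood test of edgeR; DESeq2 and the exact test of edgeR each called 1.

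Some of these lists were called under alternatives at the preset correlation, though with an estimated correlation the adjusted p was 0.993 for each. With all libraries kept, stroma was called at a camera adjusted p of 0.0348 with the replicate block, 0.0475 with upper-quartile scaling, 0.0395 with library size alone, 0.0386 on ranks, 0.0191 with the length trend removed, 0.0396 with the GC trend removed and 0.0231 with both removed. The stroma median was -0.31 without NAPQI replicate 1, -0.11 without control replicate 1 (0.237) and -0.06 without NAPQI replicate 3 (0.34). Germ cell identity was called at 0.0221 on ranks and 0.0337 with the length trend removed. Without control replicate 2 the camera adjusted p was 0.0252 for germ cell identity, 0.00809 for stroma, 0.00185 for the surface epithelium and 0.0011 for fetal testis cells. Without NAPQI replicate 1 it was 0.000694 for germ cell identity, 0.00093 for stroma and 0.0111 for erythroid cells. It was 0.00283 for endothelium without control replicate 3, where the list was higher, and 0.0246 for fetal testis cells without NAPQI replicate 2. The endothelial list mean was 4.074 log2 CPM in control replicate 3 and 3.678 and 3.275 in control replicates 1 and 2. With NAPQI it was 3.542 to 3.921. The direction of the erythroid list rested on control replicate 3, with a median of 0.36 without it, and the median was -1.62 without NAPQI replicate 1. The mesonephros median was -0.04 without control replicate 1, -0.09 without control replicate 2 and -0.10 without NAPQI replicate 2. Medians also changed sign for the surface epithelium (0.58 without control replicate 2), endothelium (-0.12 without control replicate 2), pregranulosa cells (0.05 without control replicate 1) and primordial germ cells (-0.055 without NAPQI replicate 2).

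Stress responses that an electrophile can induce were not called as lists. The 28 antioxidant targets of NRF2 had a median log2 fold change of 0.03 (camera adjusted p = 0.838), with 1 gene higher and 2 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone. The integrated stress response had a median of 0.15 (0.198, and 0.032 without control replicate 2), which turned to -0.047 without control replicate 1 and -0.036 without NAPQI replicate 3. Of its 29 genes, 3 were higher and 2 lower when adjusted over the list alone, against 1 higher, Stc2, and 0 lower over all genes by the quasi-likelihood test of edgeR. DESeq2 and the exact test of edgeR each also called 1 lower, Ppp1r15a, at adjusted p of 0.00992 and 0.0141. Chac1, which degrades glutathione, had a log2 fold change of 1.14 ± 0.36 and Vldlr, a lipoprotein receptor, one of 0.41 ± 0.12, while Atf3 was at -1.49 ± 0.41 and Ppp1r15a at -0.77 ± 0.18; these 4 had quasi-likelihood edgeR adjusted p of 0.372, 0.343, 0.31 and 0.231. Of 26 genes of glutathione and xenobiotic metabolism (median -0.05; 0.871), 1 was higher adjusted over the list alone and 0 over all genes. It was Cyp1a1, a monooxygenase induced through the aryl hydrocarbon receptor, at 0.994 ± 0.435 CPM in controls and 3.27 ± 0.125 CPM with NAPQI (edgeR adjusted p = 0.211; DESeq2 and the exact test of edgeR each called 1 gene of this list). The p53 targets had a median of -0.08 (0.948), the heat shock response -0.009 (0.981) and chaperones of the endoplasmic reticulum -0.010 (0.838).

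The remaining lists were not called either. Medians were -0.09 for the cell cycle (camera adjusted p = 0.0924), 0.004 for ribosome biogenesis and RNA polymerase I (0.838), -0.06 for glycolysis and hypoxia (0.496), -0.13 for interferon-stimulated genes (0.244), -0.15 for mitochondrially encoded genes (0.0924) and -0.014 for retinoic acid signalling (0.871). Adjusted over the list alone, 1 mitochondrial gene was lower, mt-Co3 at -1.38 ± 0.40, and 1 retinoic acid gene was higher, Aldh1a2, an enzyme of retinoic acid synthesis, at 0.45 ± 0.12, with 0 of either list called over all genes by the quasi-likelihood test of edgeR, DESeq2 or limma-voom. For mt-Co3 the groups overlapped and the controls spread widely, at 53.4 ± 42.5 CPM against 20.5 ± 3.79 CPM with NAPQI. The cell cycle list was called without control replicate 1 (3.47e-05), control replicate 3 (0.0398) or NAPQI replicate 3 (0.00207) and with the GC trend removed (0.0385), but its median was 0.07 without control replicate 2. The mitochondrially encoded list was called without control replicate 2 (0.027) or NAPQI replicate 1 (0.0489) and with the GC trend removed (0.0235). These calls of both lists were at the preset correlation, and with an estimated one the camera adjusted p was 0.993 for each. The signs of the median, the mean and the camera direction differed for 5 lists, the surface epithelium, endoplasmic reticulum chaperones, glutathione and xenobiotic metabolism, heat shock and sirtuin lists, all with a median near 0.

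**Figure D3:**
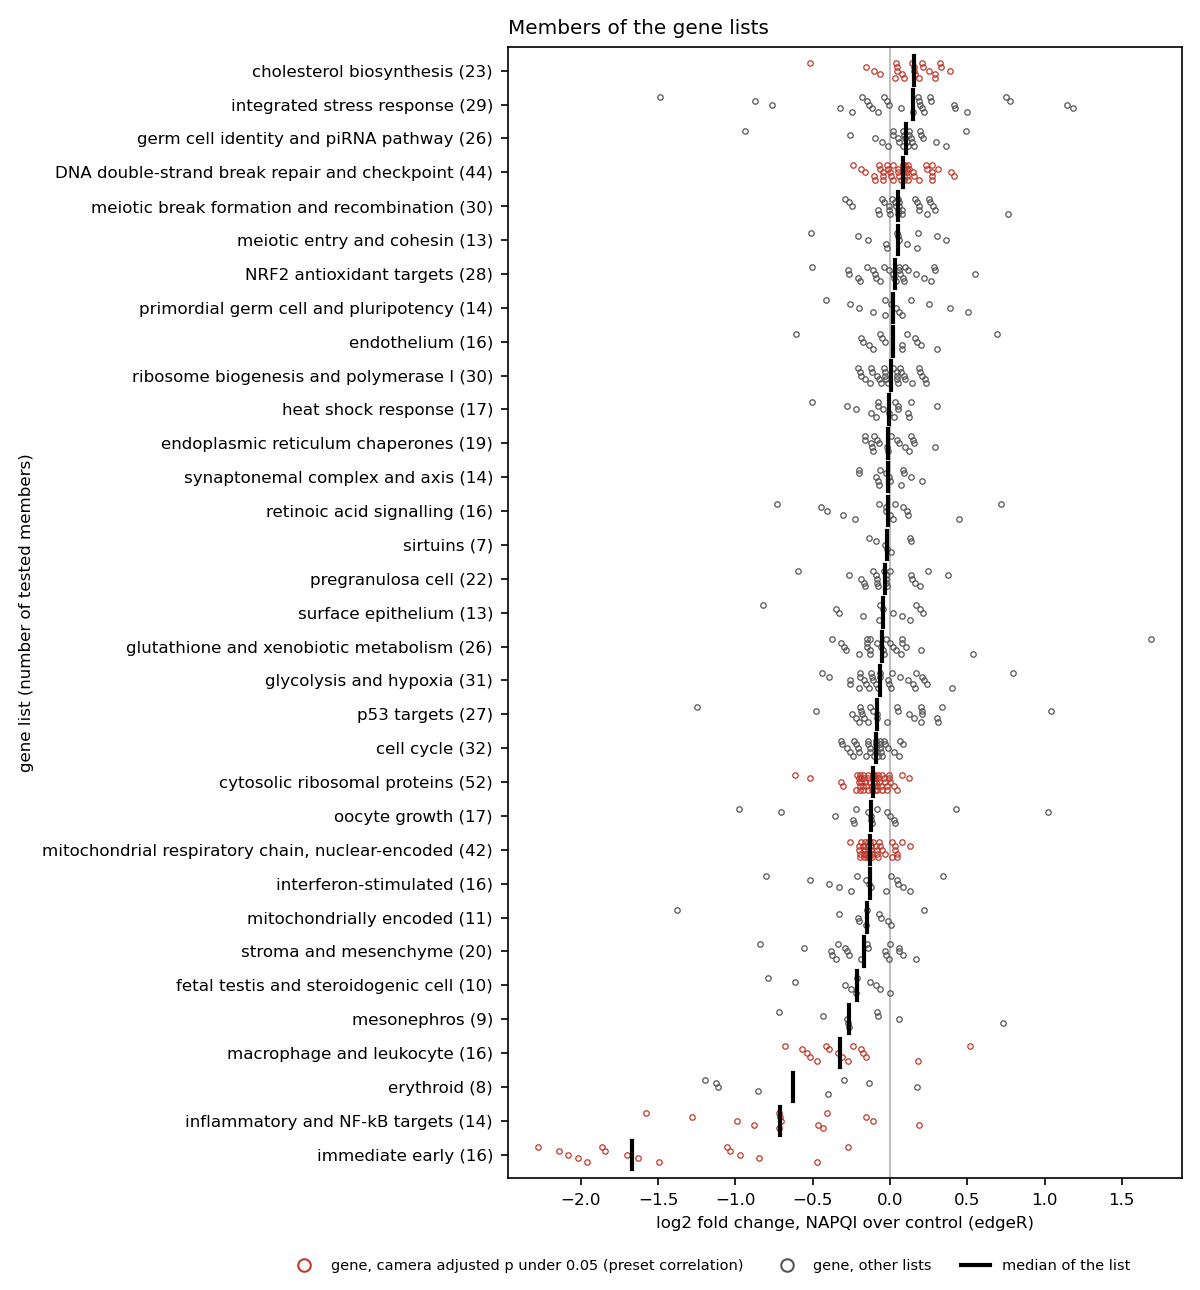
Log2 fold change (NAPQI over control, edgeR) of each tested member of the 33 gene lists, ordered by the median of the list (black bar), with the number of tested members in brackets. Red points belong to the 7 lists with a camera adjusted p under 0.05 at the preset correlation; the immediate early genes have the lowest median, -1.67, and the medians of most lists lie near 0.

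The title of the series names SIRT7, a deacylase of the sirtuin family, and the transcript was examined by itself. Sirt7 (ENSMUSG00000025138, chromosome 11, 120509198 to 120516066, minus strand) stood at 67.1 ± 6.01 CPM in controls and 60.9 ± 3.89 CPM with NAPQI. The libraries were at 66.9, 61.2 and 73.2 CPM in control replicates 1, 2 and 3 and at 64.2, 56.6 and 62.0 CPM in NAPQI replicates 1, 2 and 3. The log2 fold change was -0.14 ± 0.10, with a 95% confidence interval from -0.36 to 0.08 (edgeR adjusted p = 0.677, and 0.412 to 1 over the alternatives), which was within the spread of the libraries. The 7 sirtuin genes had a median log2 fold change of -0.02 (camera adjusted p = 0.981), and 0 had an edgeR p under 0.05 before adjustment. The span of Sirt7 overlaps Mafg, and the protein was not analysed here.

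The refit was also set beside the comparison that the authors deposited. In the authors' deposited table of 18591 genes, 23 had an adjusted p under 0.05, 21 higher and 2 lower with NAPQI. Of the 12 genes of the refit 11 were among these 23, and Ccn1, with an adjusted p of 0.549 in the authors' deposited table, was not. Stc2 led the authors' deposited table too, with a log2 fold change of 1.19. The calls of the authors' deposited table that the refit did not make included Dusp1 (log2 fold change -1.63), the fatty acid elongase Elovl6 (0.89) and the smooth muscle myosin Myh11 (0.80), chosen here after their values were seen. Log2 fold changes of the 14736 genes in both had a Pearson correlation of 0.9997 across genes, which are not independent replicates. For Sirt7 the authors' deposited table gave -0.14 with a p of 0.324. With an unadjusted p under 0.05 and an absolute log2 fold change of at least 1, the authors' deposited table held 134 genes, 72 higher and 62 lower, of which 7 were among the 12 of the refit. Another 7 of the 134 had an infinite fold change.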

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

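The removal of length and GC trends was chosen after the results were seen; the other alternatives were set before. The main count of genes was 12 (11 higher, 1 lower). It was 48 (31 and 17) with no low-count filter, 80 (52 and 28) by DESeq2, 115 (65 and 50) by the exact test of edgeR, and 1 (1 and 0) by limma-voom, by the replicate block and at an adjusted p under 0.01. An absolute log2 fold change of at least 1 left 7 genes, 6 of them higher. With the GC trend removed 0 genes were lower by edgeR, with 1228 genes at an unadjusted p under 0.05. Leaving out each library in turn gave 1 to 58 genes, 1 to 34 higher and 0 to 24 lower. The counts with other scalings, with the stricter filter and with the length trend removed were within 1.5 times the main count. The count of lists was 7, with 5 to 13 when a library was left out, and 0 with an estimated correlation and 0 by one-way fry, where 0 and 1 lists had an unadjusted p under 0.05. For the authors' deposited table, 7 of the 12 refit genes were shared under an unadjusted p with a fold change of 2, against 11 by adjusted p. Only 7 of the 12 had an absolute log2 fold change of 1 or more, so a set cut at a fold change of 2 could not share more. The cause of the other differences was not tested. Of the named genes, 0 reversed, and Sirt7 was not called under any alternative run. The 7 called lists kept their direction in all 19 alternatives run on lists, and 17 of the 26 others changed it in at least 1. Limma-voom and the exact test were not run on lists, and pseudocount alternatives did not apply to counts.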

Other observations

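The genes named next were chosen after their values were seen, from those called without NAPQI replicate 2, so that their lower level in the other NAPQI libraries was fixed by the choice. In that fit Socs3, a feedback inhibitor of cytokine signalling, was called with a log2 fold change of -2.26 (edgeR adjusted p = 0.00173). Atf3 was at -2.29 (0.0115), the antiproliferative gene Btg2 at -1.88 (0.012) and Maff, a small MAF transcription factor, at -2.00 (0.0474). With all libraries Socs3 was at -1.45 ± 0.39, Btg2 at -1.25 ± 0.36 and Maff at -1.58 ± 0.35 (quasi-likelihood edgeR adjusted p = 0.302, 0.333 and 0.192). The exact test of edgeR called Socs3 and Maff with all libraries (adjusted p = 0.0415 and 0.00381). So did the quasi-likelihood test with no low-count filter (adjusted p = 0.0407 and 0.0129). Neither called Btg2, and DESeq2 called none of these genes. Globin transcripts differed between single libraries: Hba-a1 stood at 103.68 CPM in control replicate 3 against 14.04 to 17.24 CPM in the other controls and 8.08 to 32.27 CPM with NAPQI.

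The tests on the immediate early, macrophage, ribosomal, respiratory and break repair lists were chosen after the results were seen, and what counts against a whole cause, a kept call with a bootstrap lower bound above 0.5, was widened from a bound above 0.75 after the kept shares were seen. Those on YAP and TAZ targets and on the length of the 12 genes were chosen after the gene calls were seen, but before their own values were computed, and the count over splits of the libraries was set before the data were examined.

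The ribosomal and respiratory chain lists were called lower with NAPQI at the preset correlation, but not with an estimated correlation (adjusted p = 0.993 for both). The values argue against a GC trend as the whole cause, for the respiratory list only under the widened bound. With it removed both lists stayed called at a camera adjusted p of 0.0111 at the preset correlation. Of the ribosomal median 0.987 remained (bootstrap lower bound 0.775). Of the respiratory median 0.778 remained (lower bound 0.557), so a part in the latter stays open. Without control replicate 3 the ribosomal median kept 0.117 and the respiratory median 0.188, but the lost calls had been seen first, so that this library may account for most of both shifts stays a hypothesis. A length trend is not separate from it, since control replicate 3 stood apart on length (-0.3 against -0.099 to 0.167): with the trend removed 0.209 of the ribosomal and 0.272 of the respiratory median remained. An effect of NAPQI stays open and untested.

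The macrophage list was called lower with NAPQI at the preset correlation, with 0 members called over all genes by the quasi-likelihood test of edgeR or by DESeq2 (4 at an unadjusted p under 0.05), and not with an estimated correlation (adjusted p = 0.993). A lower share of all somatic cells alike is argued against: the medians of endothelium (0.022), pregranulosa cells (-0.031) and surface epithelium (-0.048) lay above it, each with a lower quartile above its upper quartile of -0.183. Stroma, at -0.168 with a lower quartile of -0.340, did not lie apart. Fetal testis and steroidogenic cells (-0.216) and the mesonephros (-0.262), which were not part of this comparison, also had negative medians. Single libraries turned the endothelial (-0.12) and surface epithelial (0.58) medians without control replicate 2 and the pregranulosa median (0.05 without control replicate 1). A lower share of some somatic cells therefore stays open. A length trend and control replicate 3 are argued against as the whole cause only under the widened bound. At the preset correlation the list stayed called without each (camera adjusted p = 0.0337 and 0.0186). Of its median 0.76 and 0.801 remained (bootstrap lower bounds 0.614 and 0.626), so either may contribute. Fewer macrophages, or lower transcripts in them, with NAPQI stays open and untested.

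The immediate early list was called lower with NAPQI at the preset correlation, but not with an estimated correlation (adjusted p = 0.993), and 0 of its 16 members were called over all genes by the quasi-likelihood test of edgeR (14 at an unadjusted p under 0.05, 2 called by DESeq2 and 7 by the exact test). Loss of somatic cells is argued against, since the lowest median of 5 somatic marker lists was -0.323 against -1.67 for this list. The largest gap within a group, between NAPQI replicate 2 and the others, was 1.065 times the difference between the group means; the gap had been seen first, so this value does not bear on whether handling before lysis differed between cultures. The list mean of each NAPQI library lay below that of each control, with 5.694 log2 CPM in the highest NAPQI library and 5.901 in the lowest control. Handling and an effect of NAPQI both stay open.

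The break repair list was called higher at the preset correlation but not with an estimated one (adjusted p = 0.993). Of its median 0.813 remained without the length trend, where the call stayed at a camera adjusted p of 0.0462. The share was 0.679 without the GC trend (where the call ended, at 0.092) and 0.482 without control replicate 3. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 12 genes and the highest other gave 0; 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 1362 genes, and 2 others gave more: 1681 with control replicates 1 and 3 and NAPQI replicate 1 against the rest, and 1377 with control replicate 1 and NAPQI replicates 1 and 2 against the rest. All 12 genes kept over 0.75 of their log2 fold change when the length trend was removed, and all but Ptprb stayed called. The hypothesis that targets of YAP and TAZ fell as a group, raised by Ccn1 and Amotl2, was tested on the 17 other tested targets, which showed no shift as a list, with a camera p of 0.966 (0.965 with an estimated correlation) and a median log2 fold change of -0.03. Of these, Ccn2 goes with the hypothesis, at -1.10 ± 0.30 (adjusted p = 0.304 by the quasi-likelihood test and 0.0469 by the exact test of edgeR).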
